A study of Mus musculus with 8 samples.

How the data were processed

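Total RNA from 8 samples of mouse colon cancer cells was labelled with Cy3 and hybridised to 1-colour Agilent arrays, 4 of the parental line CT26 and 4 of CT26-FL3. Per the labels' protocols, CT26-FL3 was selected in mice by repeated passage through the liver, its lesions were digested, and the cells were grown briefly in culture so that stromal cells would be lost. The series' design text calls the samples independent and does not say whether they were separate cultures, so p-values measure the spread between these samples, which may be technical. Samples were grouped by the sample names in the labels. The replicate numbers in the titles run differently for CT26-FL3, so the numbers of the sample names were used.

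The authors deposited 1 table per array with the intensity of each spot, its local background intensity and a standard deviation. Agilent Feature Extraction is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited intensity already had its background subtracted, as the values show: negative controls had median intensities from 2.23 to 7.43 while the background column held medians from 21.1 to 24.4. The export has other columns than Feature Extraction's own output, so the planned processed signal was replaced by this intensity, the planned call of well above background by a limit per array, and the planned outlier flags by the mark for failed spots. The limit was 2.6 times the median standard deviation of the 153 negative control spots of that array and lay between 16.9 and 23.2. The authors also deposited a table of log2 values per probe. Each probe of it was centred on its median over the arrays (largest absolute median 9.55e-07) and its columns had equal sums. Its columns correlated with the centred array values at r from 0.990 to 0.998 over 14909 bright probes, and its column medians were -0.01, 0.00, -0.01 and 0.02 in CT26 replicates 1 to 4 and 0.00, 0.00, 0.02 and 0.00 in CT26-FL3 replicates 1 to 4. Its direction and log scale were settled by this comparison, while the exact normalization stays unknown.

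Each array held 45018 spots, of which 1639 were controls and were left out. Failed spots (3 to 76 gene spots per array) were left out, spots of 1 probe were averaged as log2 intensity, and each array's 75th percentile was subtracted. That percentile lay between 808 and 1152 intensity units, and 52.8 to 58.2% of the 41174 probes were above the limit. The number of arrays limits the precision. A probe was kept if it was above the limit on at least 4 of the 8 arrays (23068 probes). The brightest kept probe stood for a gene, which left 15097 features. Of these, 12611 had a proper symbol, meaning a known one that is not an accession, Gm number, Rik clone, LOC or ENSMUS name. Kept probes of 5641 genes numbered more than 1, and in 141 genes 2 probes passed the threshold in opposite directions. Gene names came from the platform annotation. For 32524 probes the symbol was updated through the gene identifier in a RefSeq table of the GRCm38.p6 assembly, for 140 it stood as annotated, 814 probes were named through their accession, 7651 kept the array's own name, and 45 with several genes kept the probe name. The files name no genome build, so no coordinates are given.

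The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are CT26-FL3 over CT26, given with the standard error (SE) of the log2 value and n = 4 per line. A gene with no probe above the limit on any array of a line has only a bound. It is the bright line's mean against the other line's mean of, per array, the higher of the probe's own value and the lowest signal among probes above the limit. The 25 gene lists, 19 of pathways and 6 of cell type markers, were fixed before the data were examined, as were the main model, the alternatives and the rule for named genes. Lists were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, each adjusted over the 25 lists. fry tests whether a list's genes move on balance one way and does not compare them with other genes.

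Named genes included the 12 largest rises and 12 largest falls among genes above the limit on all 8 arrays whose lines did not overlap. They also included the 5 largest bounds in each direction. Both sets were taken from genes with a proper symbol that passed the threshold. Up to 4 genes past the threshold with the largest change in each list were added. Il33, Cdh1, Vim, Epcam, Vegfa, Myc and Cxcr4 were named whatever their result. Others are said to be chosen after their values were seen. Some genes are not reported here. The arrays' file names share 1 number among replicates 1 and 2 of both lines and another among replicates 3 and 4. These sets are called batches here, although no file header gives a slide. Deviations from the line means correlated between lines at a mean of 0.13 within a batch (0.006 to 0.23) and -0.13 across batches (-0.243 to 0.092). Deviations cancel over the arrays of a line, so these means nearly mirror each other and the negative one adds nothing. Values with the batch as a block or within each batch are therefore given for Il33, for the lists that passed and where a list's call changed.

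The alternatives were quantile normalization, median centring, other filters on dim probes, the mean of a gene's probes, failed spots kept, replicate or batch blocks, a variance trend with robust estimation, the deposited log2 table and leaving out each array. A constant of 50 added before log2, a doubled limit, the arrays with the highest floor left out and fits within batches were added after seeing the data. Background correction by normexp was planned and was not run, because the intensity already had its background subtracted and the signals it starts from are not used here. The model was tested on simulated data for this comparison with the real means and spreads of 15097 features, of which 200 were changed. Of 50 features each, it recovered 18 changed by 0.3 on the log2 scale, 37 by 0.5, 48 by 1 and 50 by 2, and 6.71% of its calls were false. In the real data 7472 features passed, which makes the adjusted threshold less strict there. The arrays were also drawn without batches. These recoveries and the false share therefore do not carry over to the real comparison. In a second simulation with 1 of 25 lists shifted by 0.3, camera called that list and 0 others. Its genes were drawn independently of each other, so it cannot tell how often camera calls lists of correlated genes by mistake.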

Results

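CT26 is a colon carcinoma line from BALB/c mice that rarely forms liver metastases, and CT26-FL3 is a line selected from it for frequent ones. Gene expression was measured on 1-colour arrays in 4 samples of each line. The single comparison asks which transcripts differ between the metastatic line and its parent. Values of arrays of the same line correlated at r from 0.996 to 0.998 across genes, and those of different lines at 0.982 to 0.984; genes are not independent replicates. The first principal component held 75.8% of the variance and separated the lines, and the second held 7.25%.

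The alarm cytokine Il33 had the largest increase among the genes fixed by name in advance, of which Vegfa and Myc were the others that rose. Il33 was fixed because later work on this pair of lines deals with it, so it was not chosen blindly. It rose 36.6-fold in CT26-FL3 (log2 fold change 5.19, SE 0.18, n = 4 per line, limma adjusted p = 1.13e-07), and its probe was above the detection limit on 3 of the 4 CT26 arrays and on all 4 CT26-FL3 arrays. With a constant of 50 added before log2, which draws dim values together, the change was 3.56. It was 5.19 with the batch as a block, 5.11 within replicates 1 and 2 and 5.27 within replicates 3 and 4. Among genes detected on all 8 arrays, the peptide hormone gene Cck rose 18.5-fold (log2 4.21, SE 0.08), the acyl-CoA synthetase gene Acsl6 16.6-fold (4.06, SE 0.08), the lysosomal protease gene Ctss 15.7-fold (3.97, SE 0.13) and the tryptophan-degrading enzyme gene Ido1 14.4-fold (3.85, SE 0.08). The troponin gene Tnnt2 fell by 4.12 on the log2 scale (SE 0.08), the chloride channel family gene Clic5 fell by 4.10 (SE 0.06), and the myelin protein gene Pmp22 fell by 3.85 (SE 0.08).

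The other large rises were Rcn3 (log2 3.71), the B cell survival factor Tnfsf13b (3.63), the glutamine transporter Slc38a1 (3.36), Rhd (3.32), the matrix proteoglycan decorin, Dcn (3.32), Car6 (3.25), Prss12 (3.00) and the carbonic anhydrase Car9 (2.98). A second kept probe of Cck differed by only 0.14 and one of Tnfsf13b by 0.34. Klhl30 fell by 3.74, the tight junction protein gene F11r fell by 3.71, Ifi27l2a fell by 3.57, Anxa8 fell by 3.45 and Cul9 fell by 3.39. The sodium pump subunit gene Atp1b1 fell by 3.26, Plac9a fell by 3.20, Renbp fell by 3.09 and the complement factor gene Cfb fell by 3.04. Adjusted p-values of these 24 genes detected on all 8 arrays ranged up to 3.55e-07.

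**Figure D1:**
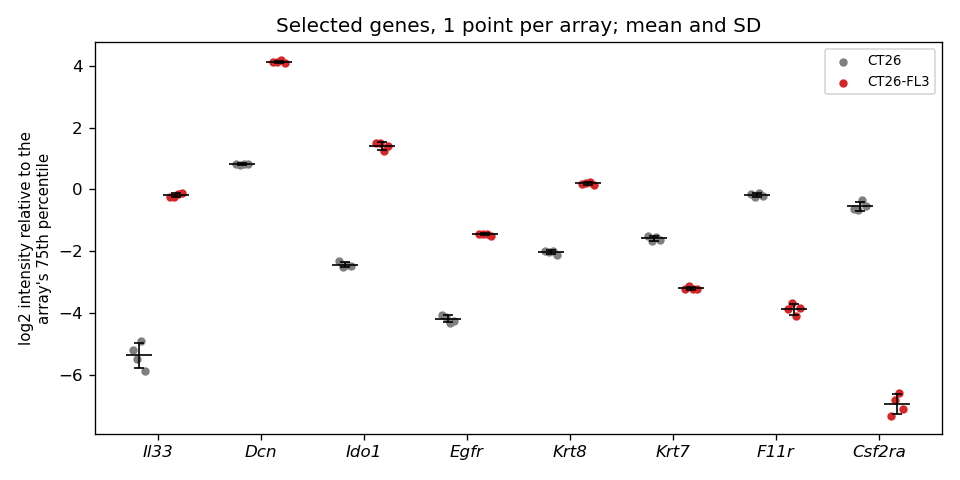
Log2 intensity relative to each array's 75th percentile for 8 genes, with 1 point per array, gray for CT26 and red for CT26-FL3; bars give the mean and SD of 4 arrays. The 4 CT26-FL3 arrays lie above the CT26 arrays for Il33, Dcn, Ido1, Egfr and Krt8, and below them for Krt7, F11r and Csf2ra. Csf2ra was not above the detection limit on any CT26-FL3 array.

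Some genes were above the limit in 1 line alone, 76 in CT26-FL3 and 66 in CT26. In CT26-FL3, Ap3b2 was at least 17.8-fold higher, Ralyl at least 16.5-fold, the peptide transporter Slc15a3 at least 10.3-fold, the transcription factor Bcl11b at least 9.96-fold and the epithelial transcription factor Grhl2 at least 6.40-fold. Transcripts not above the limit in CT26-FL3 included the GM-CSF receptor gene Csf2ra (at least 33.7-fold lower), the growth factor gene Pdgfb (at least 9.92-fold), Chst7 (at least 8.95-fold), Akr1c14 (at least 8.69-fold) and Depp1 (at least 8.22-fold).

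In all, 7472 of 15097 features passed the threshold, 3645 higher and 3827 lower in CT26-FL3 (48.8% higher). A fitted change of at least 2-fold was seen in 831, of which 467 rose and 364 fell, and at least 4-fold in 214. These counts use the fitted value also for genes that have only a bound. Some of those had bounds under 2-fold, such as Col5a2 (fitted 4.43-fold, bound 1.88-fold) and Tie1 (5.12-fold and 1.64-fold). Where probes had to be above the limit on all 8 arrays, 568 features changed at least 2-fold. The median size of a called change was 0.37 on the log2 scale. The 4 arrays of one line lay beyond those of the other for 47.4% of features, against 2.86% by chance. With the batch as a block 7518 features passed. Within replicates 1 and 2 there were 4205 and within replicates 3 and 4 there were 4183, in fits of 2 arrays against 2. With a constant of 50 added before log2, the count of at least 2-fold changes was 459.

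All named genes that were tested kept their direction in both batches, which had to follow for genes whose lines did not overlap. Within replicates 1 and 2 118 of them passed, without Apoa1, Plvap and Vegfa; Pax5 is among the 118 with 1 CT26 array, as its spot on the other failed. Within replicates 3 and 4 116 passed, without Apoa1, Cd74, Ggt1, Nlrc5 and Vegfa.

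Of the 25 gene lists, 9 passed camera, 5 higher and 4 lower in CT26-FL3, and 1 did with an estimated correlation. With the batch as a block 9 lists passed as well. fry called 21. The estimated correlation lay below the preset 0.01 for collagens and basement membrane (-0.0128), p53 targets (0.00319) and cytokines and their receptors (0.00761). A correlation above the preset value therefore cannot account for the loss of these lists. For the other lists that no longer passed, the estimate lay between 0.036 and 0.0615. With an estimated correlation camera takes its degrees of freedom from the few arrays, and with a preset one from the many genes. This alone raises the p-values of all lists. The drop from 9 lists to 1 is therefore not read as an effect of gene correlation, and the share of each was not tested.

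Cholesterol synthesis had the smallest camera p of the 25 lists. Of its 32 genes 30 fell, 0 rose and 2 did not pass, also 30 when adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, fell by 1.51 (SE 0.06), the isomerase gene Idi1 fell by 1.49 (SE 0.07), Hsd17b7 fell by 1.40 (SE 0.07) and Nsdhl fell by 1.34 (SE 0.09). The list also holds genes of fatty acid synthesis, of which, chosen after its value was seen, the fatty acid synthase gene Fasn fell by 0.74. The list's median was -0.88, and it was -0.88 within replicates 1 and 2 and -0.86 within replicates 3 and 4. The camera adjusted p was 1.43e-14, and this was the single list that passed with an estimated correlation (adjusted p = 0.0133).

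**Figure D2:**
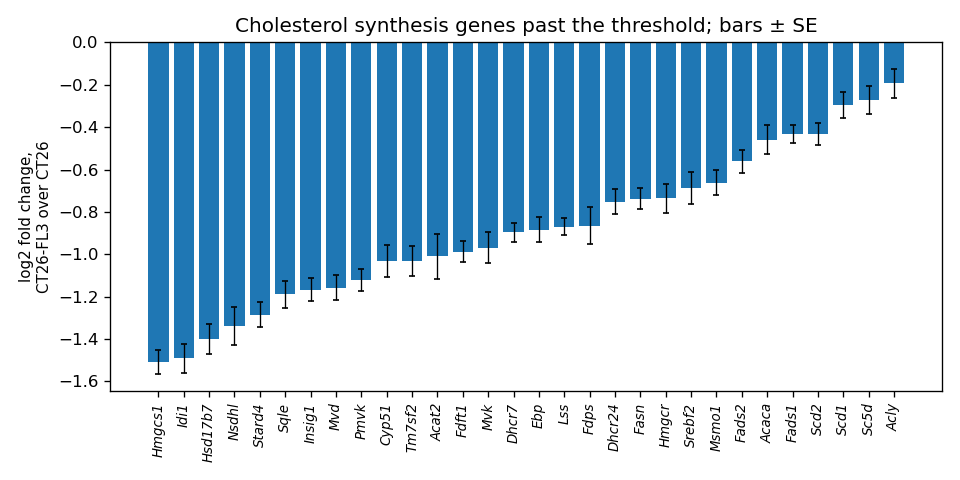
Log2 fold change of CT26-FL3 over CT26 for the 30 cholesterol synthesis genes that passed the threshold, sorted; bars give the fitted value and error bars the SE, with 4 arrays per line. All 30 bars lie below 0, with Hmgcs1 lowest at -1.51.

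Of 51 interferon response genes tested, 38 rose, 2 fell and 11 did not pass, with 38 and 2 when adjusted over the list alone. The antiviral gene Mx1 rose by 1.98 (SE 0.09), the transcription factor Irf8 by 1.16 (SE 0.07) and Rsad2 by 1.07 (SE 0.07), while Ifi27l2a fell by 3.57 (SE 0.04). The list median was 0.33 (0.32 and 0.36 within the 2 batches), with a camera adjusted p of 7.53e-09 and adjusted p = 0.0782 with an estimated correlation. Genes of antigen presentation did not pass as a list (8 rose, 4 fell and 15 did not pass, also 8 and 4 adjusted over the list alone, adjusted p = 0.49). Among them the transporter gene Tap2 rose by 0.65 and H2-DMa by 0.53. Cd74 (1.03, or 0.35 with the constant of 50, above the limit on 2 CT26 arrays) and Nlrc5 (0.61) also rose. Nlrc5 did not pass with the replicate block by title numbers (limma adjusted p = 0.0572).

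Cytokines and their receptors rose in 20 of 37 genes, fell in 8 and did not pass in 9, with 20 and 11 adjusted over the list alone. Il18 rose by 2.16 (SE 0.05), Tnfrsf11b fell by 2.32 (SE 0.11) and Il7 was at least 2.93-fold lower. The list median was 0.20 (0.19 and 0.15 within the 2 batches), the camera adjusted p was 0.0362 and adjusted p = 0.202 with an estimated correlation. The camera adjusted p of this list was 0.0907 within replicates 3 and 4, 0.0809 with the replicate block by sample-name numbers and 0.081 with the block by title numbers, and it lay between 0.00109 and 0.0907 over the alternatives that kept the preset correlation. Chemokines and receptors were split, with 8 higher, 8 lower and 5 not past the threshold of 21 (8 and 8 adjusted over the list alone, adjusted p = 0.703). Cxcl5, above the limit on 1 CT26 array, rose by 2.42 (0.93 with the constant of 50), and Cxcr3 was at least 3.86-fold higher. Ccl9 was at least 7.18-fold lower and Ccl20 at least 2.89-fold lower. Cxcr4 was not above the limit on any array.

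Of 41 genes of ATF4 and endoplasmic reticulum stress, 24 rose, 6 fell and 11 did not pass (24 and 8 adjusted over the list alone). The stress transcription factors Atf3 and Ddit3 rose by 2.06 (SE 0.05) and 1.73 (SE 0.05) and Trib3 by 1.33 (SE 0.06), while the chaperone complex gene Sdf2l1 fell by 1.37 (SE 0.05). The list median was 0.25 (0.25 and 0.26 within the 2 batches), the camera adjusted p was 0.000817 and adjusted p = 0.202 with an estimated correlation. Of 26 p53 targets 14 rose, 5 fell and 7 did not pass (15 and 5 adjusted over the list alone). Gadd45a rose by 2.52 (SE 0.06), Btg2 by 1.14 (0.67 on the lowest of its 3 kept probes), Mdm2 by 1.10 and Plk3 by 0.99. Their median was 0.22 (0.20 and 0.25 within the 2 batches), the camera adjusted p was 0.00468 and adjusted p = 0.0796 with an estimated correlation.

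Hypoxia and glycolysis genes rose in 23 of 40 cases, fell in 8 and did not pass in 9 (24 and 8 adjusted over the list alone). Besides Car9, Car12 rose by 1.74 (SE 0.08) and Ankrd37 by 1.32 (SE 0.05), and Stc2 fell by 0.98 (SE 0.04). The list median was 0.23 (0.21 and 0.20 within the 2 batches), the camera adjusted p was 0.0165 and adjusted p = 0.233 with an estimated correlation. With the mean of a gene's probes the camera adjusted p was 0.0618, in a range of 0.000743 to 0.0618 over the alternatives with the preset correlation. Vegfa differed by 0.14 (SE 0.04, adjusted p = 0.0274), and it no longer passed in several alternatives, for example with median centring (adjusted p = 0.0971). Over all alternatives its adjusted p lay between 0.0075 and 0.26.

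Of 58 cell cycle genes, 28 fell, 1 rose and 29 did not pass (29 and 1 adjusted over the list alone). The transcription factor E2f2 fell by 1.48 (SE 0.06), Ccne2 fell by 1.02 (SE 0.15), Cdc25b fell by 0.52 (SE 0.06) and Cdc6 fell by 0.44 (SE 0.06) on the brighter of its 2 kept probes, while the other differed by less than 0.01. The list median was -0.17 (-0.16 and -0.19 within the 2 batches), the camera adjusted p was 0.000817 and adjusted p = 0.205 with an estimated correlation. NRF2 and detoxification genes fell in 20 of 39 cases, rose in 7 and did not pass in 12 (21 and 7 adjusted over the list alone). The quinone reductase gene Nqo1 fell by 1.82 (SE 0.06), Mgst3 fell by 1.68 (SE 0.05), Gsta1 fell by 1.49 (SE 0.14) and Aldh1a7, above the limit on 1 CT26-FL3 array, fell by 3.07 (SE 0.08), or 1.46 with the constant of 50. Their median was -0.17 (-0.16 and -0.18 within the 2 batches), the camera adjusted p was 0.0169 and adjusted p = 0.309 with an estimated correlation.

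Collagens and basement membrane genes fell in 20 of 32 cases, rose in 4 and did not pass in 8 (21 and 4 adjusted over the list alone). Col4a5 fell by 1.93 (SE 0.08), Col12a1 was at least 5.47-fold lower and Col5a2 at least 1.88-fold lower, and Dcn rose by 3.32 (SE 0.04). The list median was -0.26 (-0.30 and -0.27 within the 2 batches), the camera adjusted p was 0.00358 and adjusted p = 0.0782 with an estimated correlation.

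**Figure D3:**
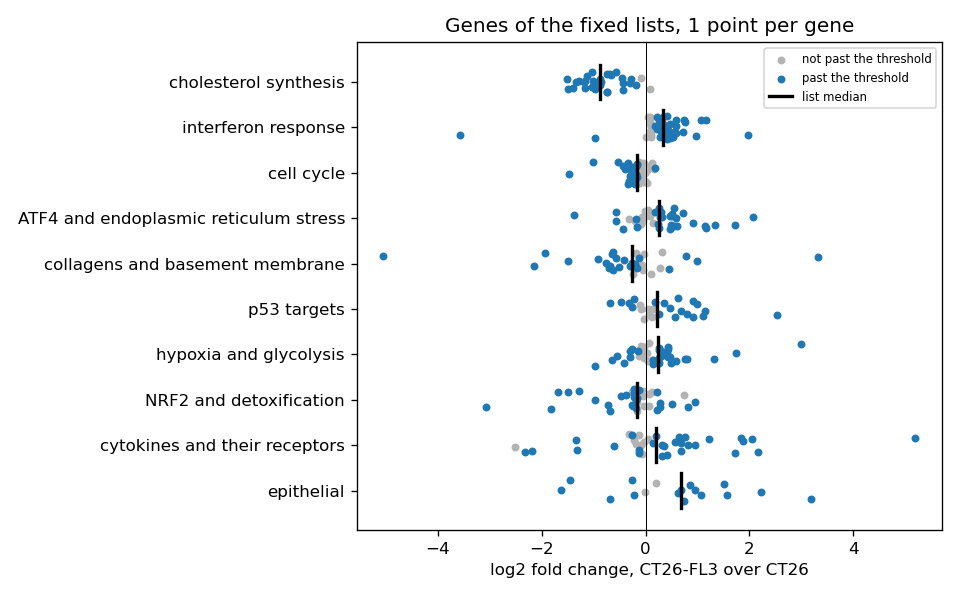
Log2 fold change of CT26-FL3 over CT26 for the genes of the 10 pathway lists with the smallest camera p, with 1 point per gene, blue past the threshold and gray not, and a black line at the list median. Nearly all cholesterol synthesis genes lie below 0 (median -0.88) and most interferon response genes above it (median 0.33).

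Epithelial genes rose in 10 of 17 cases, fell in 5 and did not pass in 2 (10 and 5 adjusted over the list alone), and 18 of the 35 fixed genes were not tested. The list did not pass (median 0.69, adjusted p = 0.0985); it passed within replicates 1 and 2 (median 0.72, adjusted p = 0.0481) and not within replicates 3 and 4 (0.61, adjusted p = 0.111), in a range of 0.0481 to 0.377 over the alternatives with the preset correlation. The simple keratin genes Krt8 and Krt18 rose by 2.23 (SE 0.05) and 1.56 (SE 0.09), and Krt7 fell by 1.63 (SE 0.05). Cdh1 and Epcam were not above the limit on any array. Mesenchymal genes were split (7 rose, 8 fell and 9 did not pass, 8 and 8 adjusted over the list alone, adjusted p = 0.975). Tenascin C, Tnc, above the limit on 1 CT26 array, rose by 4.14 (SE 0.13), or 2.33 with the constant of 50. Tgfbi and Tgfb2 fell by 0.98 and 0.96, Loxl2, above the limit on 1 CT26-FL3 array, fell by 2.08 (0.65 with the constant), and the intermediate filament gene Vim fell by 0.40 (SE 0.07). The median of this list was -0.02, its mean 0.05 and the direction of its test up.

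Wnt targets rose in 9, fell in 8 and did not pass in 4 of 21 cases (10 and 9 adjusted over the list alone, adjusted p = 0.845). Axin2 was at least 1.83-fold lower, Bmp4 fell by 1.24, Wnt10a fell by 0.99 and Myc rose by 0.84 (SE 0.07). TGF-beta and YAP targets rose in 7, fell in 12 and did not pass in 10 of 29 (7 and 13 adjusted over the list alone, adjusted p = 0.299). Smad6 fell by 1.09, Id1 fell by 1.01, Ccn2 fell by 1.00 and Edn1 was at least 1.74-fold lower. Of 25 colorectal stem cell and receptor genes 7 rose, 12 fell and 6 did not pass, also adjusted over the list alone (adjusted p = 0.877). The receptor gene Egfr rose by 2.73 (SE 0.06; the lowest of its 4 kept probes gave 1.41), its ligand gene Btc by 1.60 and Alcam by 1.00, and Cd24a fell by 0.98. The median of this list was -0.11 and its mean 0.14.

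Markers of other cell types that the excised lesions could have held did not pass camera as lists, although the T, NK and B cell markers did in 2 alternatives with the preset correlation. fry called the lists of fibroblasts (adjusted p = 7.14e-06), endothelial cells (adjusted p = 0.00936) and T, NK and B cells (adjusted p = 0.000272) higher and that of cholangiocytes lower (adjusted p = 2.28e-06), and not those of macrophages (adjusted p = 0.0616) and hepatocytes (adjusted p = 0.598). Of 12 tested fibroblast and stellate cell markers 2 rose and 6 fell (also adjusted over the list alone, adjusted p = 0.474): Dcn rose, Fap rose by 0.93, Col1a1 fell by 0.76 and Cygb fell by 0.74. The median of this list was -0.15 and its mean 0.09. Of 12 macrophage and Kupffer cell markers 4 rose and 2 fell (also adjusted over the list alone, adjusted p = 0.735). Mrc1 rose by 0.99 and Mpeg1 by 0.89, while Cd14 fell by 1.45 and Lyz2 was at least 2.03-fold lower. Their median was 0.08 and their mean -0.05. Of 5 T, NK and B cell markers tested, out of 20, 2 rose and 0 fell (also adjusted over the list alone, median 0.23, adjusted p = 0.0985). This list passed with the block by title numbers (median 0.40, adjusted p = 0.0101) and without CT26 replicate 1 (0.28, adjusted p = 0.0292), in a range of 0.0101 to 0.618 over the same alternatives. The kinase gene Lck rose by 2.28 (SE 0.08). Pax5 rose by 2.86 over 3 CT26 arrays, since the spot of CT26 replicate 1 was marked as failed; with that spot kept the change was 1.84 and the adjusted p 0.115. Over all alternatives the adjusted p of Pax5 lay between 2.99e-10 and 0.116.

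Of 8 endothelial markers 2 rose and 0 fell (also adjusted over the list alone, adjusted p = 0.49), with Tie1 at least 1.64-fold higher and Plvap higher by 0.29. Of 8 cholangiocyte markers 2 rose and 3 fell (also adjusted over the list alone, adjusted p = 0.735). Onecut1 rose by 0.76 and Ggt1 by 0.57, and the water channel gene Aqp1 fell by 2.69 (SE 0.05). Their median was 0.11 and their mean -0.38. Of 6 hepatocyte markers 1 passed, Apoa1 with 0.24 (adjusted p = 0.0234), and 0 passed adjusted over the list alone (list adjusted p = 0.899). Apoa1 no longer passed in several alternatives, for example without a filter on dim probes (adjusted p = 0.0823), with a range of 0.0119 to 0.148 over all alternatives. Of the 23 hepatocyte markers on the array 15 were above the limit on 0 CT26-FL3 arrays.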

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

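The test on cell type markers was chosen after the result was seen. In 15 of 255 groups of 4 arrays, 1 array lay further from the others, relative to the group's range, than Dixon's critical value for 4 samples. Chance gives about 1 in 20.

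Array measures held 1 such case: CT26-FL3 replicate 4 had 76 failed gene spots against 3 to 12 in the other arrays of its line (ratio 0.877). Among CT26 arrays, replicate 4 stood apart for Ralyl (0.88), Chst7 (0.967) and Apoa1 (0.916), replicate 2 for Akr1c14 (0.929), Nlrc5 (0.831) and Lyz2 (0.835), and replicate 1 for Plk3 (0.845). Ralyl was above the limit on 0 CT26 arrays, so its values there are floor values. The lowest intensity was 6.10 on CT26 replicate 4 and 1.87 to 3.33 on the other CT26 arrays. Among CT26-FL3 arrays, replicate 4 stood apart for Ggt1 (0.847), Tgfb2 (0.949), Mgst3 (0.909) and Pax5 (0.967), replicate 2 for Krt7 (0.936) and Vegfa (0.939), and replicate 1 for Cd14 (0.898).

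The number of changed genes was compared with other ways to part the 8 arrays into 4 and 4. Of the 35 splits 1, the real one, gave 7472 genes, and the highest other gave 1 gene. For changes of at least 2-fold the real split gave 831 and the highest other 1, so that 1 of 35 splits was as large. For the lists past camera the real split gave 9 and the highest other 6, again with 1 of 35 as large. This argues against chance in the grouping of these 8 arrays for these 3 counts. It does not exclude it, since 1 of 35 is the smallest share that 35 splits can give. Chance differences between cultures are not excluded either. Splits that mix the lines carry the line difference in their residual spread, which lowers their counts. The 16 splits that exchange 1 array of each line gave 3 to 6 lists, and the 18 that exchange 2 gave 0 to 1.

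The fall of cholesterol synthesis genes was set against a trend with probe brightness and against the scaling of the arrays. Of 10000 random lists of 32 genes matched on brightness, 0% had a median as low as -0.88, and the lowest was -0.24, which argues against such a trend. Under quantile normalization and median centring the higher of the list's medians was -0.85. The median over all genes was -0.0055 in the main fit, 0.0099 with quantile normalization and 0.0095 with median centring. Such small shifts could hardly have moved the list, so no conclusion on the scaling is drawn from this. A difference between the lines and a difference in the state of the cultures at harvest both stay open and may each account for it.

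Cell type markers that rose in CT26-FL3 could come from liver, stromal or immune cells left over from the lesions, although the labels describe a culture step to remove stromal cells. The highest share of markers above the limit on all CT26-FL3 arrays and higher there was 16.7%, for macrophages. A small share of such cells could raise only a few markers, so this share excludes nothing. Of the 13 markers called higher, all but Tie1 also had a probe above the limit on 3 or 4 CT26 arrays. Their presence was thus not particular to CT26-FL3, which leaves the source of the rise open. Lyz2 and Cd14 were lower in CT26-FL3, as was Col1a1, while Dcn was higher. fry called the fibroblast list higher, although 6 of its 12 tested markers fell and 2 rose. With Dcn at 3.32 the list's mean was 0.09 and its median -0.15, so that call may rest on Dcn. Alb, Ptprc and Lum were above the limit on 0 arrays of either line and were not tested. Markers above it on 0 CT26-FL3 arrays were 15 of 23 for hepatocytes, 13 of 24 for macrophages and 13 of 20 for T, NK and B cells. They were 8 of 21 for fibroblasts, 7 of 20 for endothelial cells and 4 of 13 for cholangiocytes. Leftover cells and a difference between the lines both stay open.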

How the results depend on the processing

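The fits within batches, the added constant, the doubled limit and the fit without the high-floor arrays were chosen after seeing the data. Apart from the values that follow, the counts of genes and lists stayed within 1.5 times of the main ones under the alternatives run. Within replicates 1 and 2 the count was 4205 and within replicates 3 and 4 it was 4183, in fits with fewer arrays, and with the constant of 50 the count of at least 2-fold changes was 459, as a constant draws dim genes together. Lists past the set test numbered 1 with an estimated correlation and 21 with fry, which asks another question. Il33 kept its call wherever it was tested, and was 3.56 with the constant; it was not tested where all 8 arrays had to be above the limit.

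The share of higher among called genes was 51.8% with quantile normalization, 52.8% with median centring, 47.3% with the mean of a gene's probes, 53.3% with the block by title numbers, 51.2% with the deposited log2 table, and 51.5% and 51.4% within the 2 batches; the cause was not tested. Leaving out 1 array at a time gave 47.9 to 50.5%. Of 2835 values of 120 named genes under the alternatives, 2811 kept direction and side of the threshold, 24 in 7 genes no longer passed, and 0 reversed. A gene whose lines did not overlap could not reverse where arrays were only left out. Leaving out 1 array gave 6808 to 7123 genes, 812 to 836 at least 2-fold changes, 9 to 10 lists and Il33 changes of 5.02 to 5.35.

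Deviations of same-numbered samples correlated at 0.12, 0.11, 0.01 and 0.17, not all above 0.1, and CT26 replicate 1 correlated best with CT26-FL3 replicate 2 (0.23), a sample of its own batch, so the numbers are not read as pairs. With the replicate block by sample-name numbers 6932 genes and 8 lists passed, and with the replicate block by title numbers, over 6 arrays, 5575 genes and 9 lists. Normexp was not run. Low signal over background limits what can be said of genes near the detection limit. Those above it on 0 arrays of a line have only bounds. Besides the genes with such a value beside their result, the named genes that follow moved by over 1.5 times with a setting, some of them above the limit on all 8 arrays. With the constant of 50 the changes were 0.96 for Adamts4, 0.96 for Krt18, 0.56 for Fap, 0.46 for Onecut1 and 0.41 for Mrc1, and -0.34 for Cd24a, -0.45 for Tgfb2, -0.45 for Cygb, -0.67 for Gsta1, -1.39 for Tnfrsf11b, -1.46 for Itga10, -1.88 for Renbp, -2.19 for Cul9 and -2.36 for Klhl30. With the mean of a gene's probes they were 2.17 for Cck, 1.99 for Tnfsf13b and -0.22 for Cdc6.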

Other observations

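Matrix proteases and inhibitors changed in both directions: of 35 genes 9 rose, 15 fell and 11 did not pass (also 9 and 15 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.496). The gelatinase gene Mmp2 rose by 2.38 on the log2 scale (SE 0.05) and the aggrecanase gene Adamts4 by 1.81 (SE 0.07), beside the rise of Ctss, and Adam12 was at least 3.30-fold lower. Integrins were also split (5 rose, 8 fell and 5 did not pass of 18, 6 and 8 adjusted over the list alone, adjusted p = 0.669). Itga10 fell by 2.74 and was above the limit on 3 CT26-FL3 arrays, Itga1 was at least 1.73-fold lower, Itgb2 rose by 1.48 (SE 0.04) and Itgb8, above the limit on 1 CT26 array, rose by 1.23 (0.40 with a constant of 50 added before log2).

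Angiogenesis factors rose in 14, fell in 12 and did not pass in 10 of 36 cases (14 and 12 adjusted over the list alone, adjusted p = 0.975). Besides Pdgfb, the related gene Pdgfc fell by 2.87 (SE 0.10) and the receptor gene Nrp1 fell by 2.74 on the brighter of its 2 kept probes, above the limit on 2 CT26-FL3 arrays, while the other, above it on 3, gave -1.91; with the constant the change was -1.31. The growth factor gene Hgf rose by 2.75 (SE 0.25) and was above the limit on 2 CT26 arrays; with the constant it was 1.16.

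Neighbouring genes were examined in the gene order of the GRCm38.p6 assembly, with windows of 25 tested genes. The largest absolute window median was 0.48 on the log2 scale, and 0 of 100 shuffled gene orders reached it, although the highest of them came to 0.46. The windows beyond every shuffle covered 1 stretch of 35 genes from Smim13 to Bicd2, chosen after its values were seen, in which 24 genes fell and 3 rose in CT26-FL3 (median -0.29). A lower copy number or another regional difference between the lines may account for it, and no DNA measurement was used here to tell these apart.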
